A study of Arabidopsis thaliana with 9 samples.

How the data were processed

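Anthers of Arabidopsis thaliana at stages 4 to 7 were profiled on Affymetrix arrays in 9 samples: wild type (Columbia, per the labels), dyt1 mutants and ams mutants, with 3 samples each that the labels describe as biological replicates. DYT1 and AMS encode bHLH transcription factors of the tapetum, the innermost anther wall layer that feeds the developing pollen. The deposited values are log2 expression values per probe set, made with RMA per the submitters' processing notes, with no version given; RMA corrects background, quantile normalizes probe signals and summarises them per probe set. Whether all 9 arrays were normalized in a single run is not given in the sources used here. The values carry no detection calls, so a level near the bottom of the scale cannot be told from background, and folds of dim probe sets are compressed. A group mean within or under the range of the arrays' lower quartiles (4.58 to 4.77) is taken here as not told from background; no fold is given for such genes, and their log2 changes are differences of signal.

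The table held 22810 probe sets. The 64 control probe sets were left out of the tests except in 1 alternative that kept them, which left 22746. They were used to describe the arrays and to define the library sets. The platform annotation given with the table listed 14016 of these, 13513 with 1 gene and 503 with several, and did not list 8730, which are unnamed here. Of the 1-gene probe sets, 13436 matched a RefSeq gene of the TAIR10.1 assembly by gene ID and took its symbol, and 77 kept the annotation's name. A gene was represented by its probe set with the highest mean over the 9 arrays, which gave 13355 genes; 147 genes had more than 1 probe set, and in 1, 7 and 25 of them the probe sets differed in their call in dyt1 against wild type, ams against wild type and dyt1 against ams. The build used to design the array is not named, so no coordinates are given and neighbouring genes were taken only by their order.

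Group means were fitted over all 9 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, which pools the spread of the 3 groups, and dyt1 against wild type, ams against wild type and dyt1 against ams were tested with Benjamini-Hochberg adjustment over 22746 probe sets per comparison. A probe set was called at an adjusted p under 0.05, without a fold limit; counts with a 2-fold limit are given beside. All adjusted p values of single genes come from limma's moderated test, and the number of arrays limits the precision. On data simulated with the real means and spreads, with 200 changed probe sets among 22746, 26%, 81% and 93.5% were recovered at 2-, 4- and 8-fold in dyt1 against wild type, 26%, 77.5% and 94% in ams against wild type, and 33%, 85% and 95.5% in dyt1 against ams.

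Gene lists were fixed before the data were examined: 21 lists of 295 genes, of which 59 genes had a named probe set, and 19 families defined by annotated names. The 9 lists with at least 3 measured genes and the families with at least 5 were tested with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry; the adjustment ran over 27 list tests and, separately, over 36 family tests. The fry values given are of its directional test. Its mixed test, which ignores direction, passed for every set called by camera except the plastid-encoded genes. The mixed test also passed for sets that camera did not call, such as tapetum transcription factors in dyt1 against ams (fry mixed adjusted p = 0.00974). The group of 69 plastid-encoded genes was added after seeing the data. The rule for named genes, also fixed before the data were examined, took AMS and DYT1, the 10 genes that rose most and the 10 that fell most in each mutant against wild type (5 and 5 for dyt1 against ams) among genes at an adjusted p under 0.05 whose 3 values did not overlap the other group's 3, and up to 4 called genes per list with the smallest adjusted p. Each of the 47 genes it named had 1 probe set. Genes named outside this rule were chosen after their values were seen.

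The labels number the samples 1 to 3 in each genotype, and the fit without the number as a block was the planned one. Alternatives covered normalization, centring, a floor and a filter on dim probe sets, variance models, array weights, the groups entering the fit, thresholds, genes near the mutated loci and leaving out each array. Blocks and subsets by library set, meaning arrays with 25S ribosomal RNA signal above or below 11 with or without a further separation by spike-in level, and the joint omission of wild type 3 and dyt1 2 were chosen after seeing the data. The simulated overlap of lists of the same sizes was also added then. A block for slide or scan date was not run, since neither was used here.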

Results

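Expression was measured in dissected anthers of wild type, dyt1 and ams plants, with 3 arrays per genotype, to ask which genes depend on each tapetal transcription factor and which changes the 2 mutants share. The array medians lay between 6.75 and 6.94 on the log2 scale.

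The arrays fell into sets that cut across the genotypes. The 25S ribosomal RNA control probe set stood at 5.51 and 9.59 in wild type 1 and 2 and at 7.42 and 6.20 in dyt1 1 and 3, against 12.4 in wild type 3, 11.5 in dyt1 2 and 11.6 to 12.4 in the ams arrays. Plastid-encoded genes followed the same division, with medians between 9.28 and 10.3 in those 4 arrays and of 8.49 in wild type 3, 7.76 in dyt1 2 and 7.86 to 8.25 in ams. The difference between the 3' and 5' probe sets of actin, a sign of RNA quality, was 1.04 to 1.38 in those 4 arrays, 2.81 in wild type 3, 2.103 in dyt1 2 and 2.67 to 2.92 in ams. The poly-A RNA spike-ins averaged 3.85 and 3.76 in wild type 1 and 2 and at least 6.67 in the other 7 arrays. Across probe sets, which are not independent replicates, wild type 1 and 2 correlated at 0.989 but only at 0.939 and 0.930 with wild type 3; dyt1 1 and 3 correlated at 0.992 but at 0.929 and 0.939 with dyt1 2; and the ams arrays correlated at 0.983 to 0.985.

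**Figure D1:**
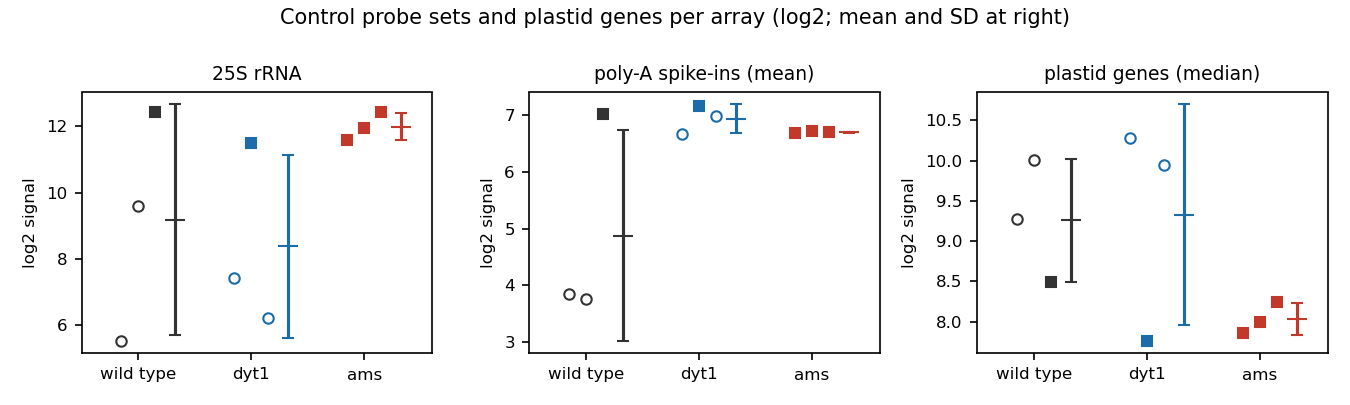
Log2 signal of the 25S ribosomal RNA control probe set, the mean of the poly-A spike-in probe sets and the median of 69 plastid-encoded genes in each of the 9 arrays; filled squares mark arrays with high 25S signal, open circles arrays with low 25S signal, and bars the mean and SD of 3 arrays. Wild type 3 (12.4) and dyt1 2 (11.5) share the high 25S signal of the ams arrays.

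AMS, the gene mutated in ams, stood at 7.73 ± 0.19 (SD, n = 3) in wild type, 4.80 ± 0.85 in dyt1 and 9.45 ± 0.14 in the arrays labelled ams. It fell by 2.93 on the log2 scale in dyt1 (SE 0.36, limma adjusted p = 0.0288) and rose by 1.72 in ams (adjusted p = 0.0413), and dyt1 lay below ams by a log2 difference of -4.65 (adjusted p = 0.000288). In dyt1 the adjusted p was 0.164 and 0.0841 without wild type 1 or 2, 0.135 without dyt1 3, and 0.0561, 0.0645 and 0.0737 without ams 1, 2 or 3. In ams it was 0.118 and 0.125 without wild type 1 or 2, 0.0772 without dyt1 3, 0.146, 0.132 and 0.109 without ams 1, 2 or 3, and 0.0517 with each array centred on its median. Where the AMS probe set lies relative to the ams lesion is not given in the sources used here, so its level checks nothing about the ams label. DYT1 was not named by any probe set of the annotation used and was not analysed here.

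**Figure D2:**
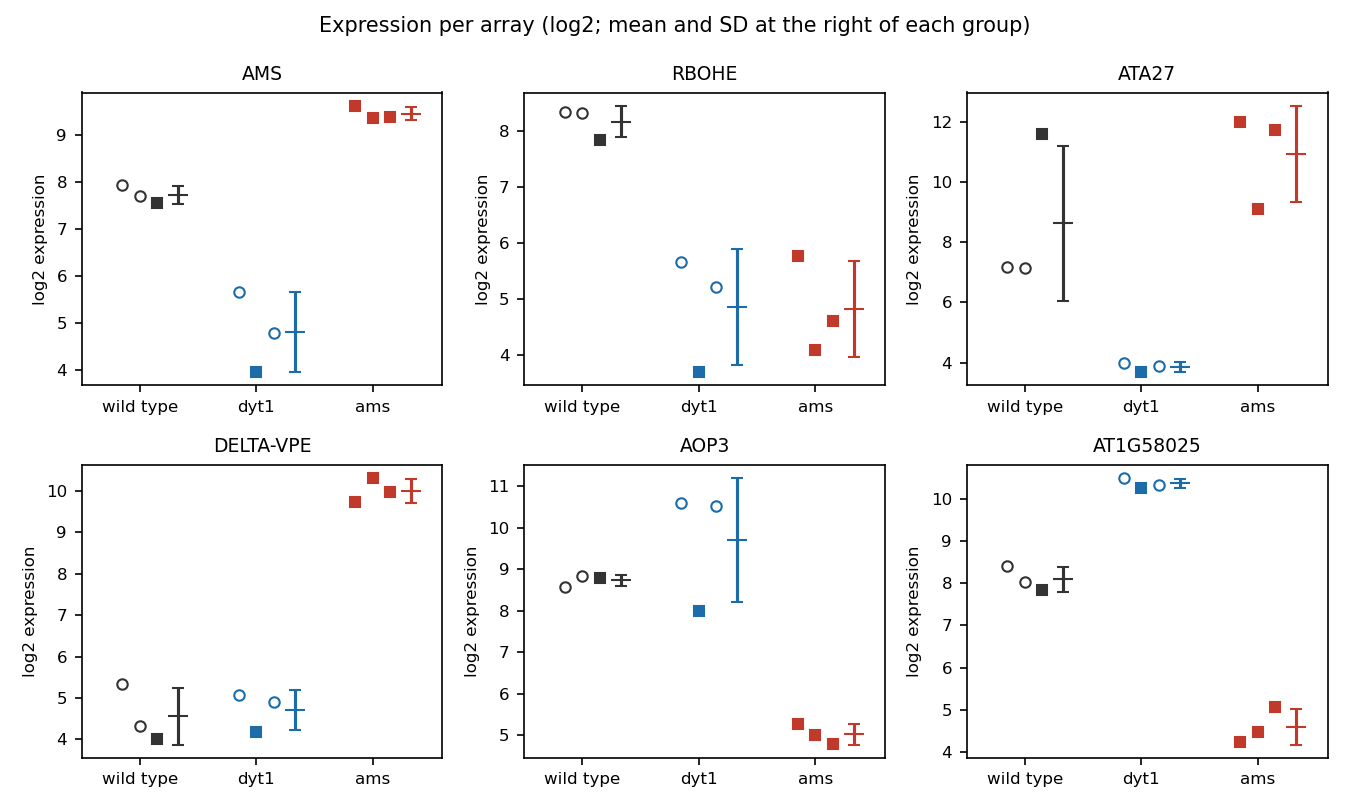
Log2 expression of AMS, RBOHE, ATA27, DELTA-VPE, AOP3 and AT1G58025 in each array of the 3 genotypes (filled squares, high 25S signal; open circles, low 25S signal), with the mean and SD of 3 arrays at the right of each group. ATA27 reached 11.6 in wild type 3 against 7.16 and 7.13 in wild type 1 and 2, and 3.69 to 4.00 in the dyt1 arrays; DELTA-VPE lay between 9.72 and 10.3 in ams and at most at 5.33 in the other arrays.

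In dyt1 anthers, few genes changed beyond the spread between arrays, and whether more rose or fell depended on the arrays and settings used. AT3G25260 fell most (log2 change -3.68, 12.8-fold, adjusted p = 0.0433), followed by AT1G28710 (-3.09), AT1G06250 (-2.96) and AMS (-2.93). AT1G65560 (-2.07), AT1G69790 (-1.97), AT3G23880 (-1.95), AT1G12600 (-1.91), AT1G07795 (-1.87) and AT5G50030 (-1.78) also fell, with adjusted p values from 0.00498 for AT1G69790 to 0.0491 for AT5G50030. AT2G16960 rose from 4.21 ± 0.24 to 7.40 ± 0.77 (log2 change 3.19, SE 0.34, adjusted p = 0.0200). AT1G35650 rose by 2.504 (adjusted p = 0.00854). AT1G42705 (2.27), AT1G58025 (2.27), AT4G03156 (2.26), the beta-expansin EXPB1 (1.84), AT4G22390 (1.69), AT1G49580 (1.34), scpl46, a serine carboxypeptidase-like protein (1.24), and AT2G30120 (1.19) also rose. Shared probe sets represent AT1G35650, AT1G42705 and AT4G22390, which may also read related genes. AT1G06250, AT5G50030, AT2G16960, AT1G35650 and AT4G03156 had a wild-type or dyt1 mean that cannot be told from background, so the size of their change is not measured beyond the difference of signal.

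Tapetal genes had large but uneven differences in dyt1. Of the 5 measured tapetum transcription factors, AMS fell and 4 did not pass, among them BHLH089 (-1.17, adjusted p = 0.611) and ROXY2 (0.72, adjusted p = 0.438); adjusted over the list alone, again only AMS fell. None of the 8 measured genes of tapetal lipid transfer and the pollen coat passed over all probe sets, and 4 fell when adjusted over the list alone. AT5G52160 had a log2 difference of -5.18 (adjusted p = 0.0549), ATA27, an anther beta-glucosidase, -4.77 (adjusted p = 0.152), AT1G66850 -4.37 (adjusted p = 0.143) and A9, a classic tapetum-specific gene, -4.12 (adjusted p = 0.251). As a set, this list was lower in dyt1 (median -3.54, 6 of 8 genes lower, camera adjusted p = 0.00685). It was not called with an estimated correlation (adjusted p = 0.985) or by fry (adjusted p = 0.203). With library set as a block the list's shift was -3.54 (adjusted p = 0.00966). The block cannot move this estimate, since wild type and dyt1 hold the same mix of low and high 25S arrays. The shift was -1.88 within the arrays of low 25S signal (camera adjusted p = 0.000691), where genotype cannot be told from spike-in level. In the arrays of high 25S signal, dyt1 2 alone against wild type 3 alone, it was -6.30, given as a value with no test. A9 stood at 11.1, 4.68 and 10.8 in dyt1 1, 2 and 3, against 12.9 to 13.1 in wild type. Without dyt1 2 the list's shift was -1.92 (adjusted p = 0.0491), without wild type 3 it was -3.27 (adjusted p = 0.0686), and without both wild type 3 and dyt1 2 it was -1.88 (adjusted p = 0.410).

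Other groups held few or no called genes in dyt1. RBOHE, an NADPH oxidase tied to tapetal cell death, had a difference of -3.31 (adjusted p = 0.0650), and 0 of the 3 measured cell death genes passed, with 1 lower when adjusted over the list alone. KNS4, a galactosyltransferase needed for pollen exine, and SWEET8 were the 2 measured exine genes and had differences of -3.69 (adjusted p = 0.224) and -0.68 (adjusted p = 0.579), with 1 lower when adjusted over the list alone. The 8 meiosis genes had a median of 0.08, with 5 higher and 3 lower and 0 called by either adjustment; camera, which sets the list against all other genes, gave the opposite sign (adjusted p = 0.968), as it did for maturing pollen. The 17 genes of the sugar transporter family are SWEET transporters except for SWEETIE, and had a median of -0.68 with 14 lower and 0 called singly. SAG29, which encodes SWEET15, differed by -3.08 (adjusted p = 0.0650) and SWEET11 by -1.40 (adjusted p = 0.116); camera called the set (adjusted p = 0.000148), but not with an estimated correlation (adjusted p = 0.787), by fry (adjusted p = 0.201) or without dyt1 2 (median -0.27, adjusted p = 0.121). This family's shift was -0.68 with library set as a block (adjusted p = 0.000202), an estimate that the block cannot move. It was -0.53 within the low 25S arrays (adjusted p = 0.0160), where genotype cannot be told from spike-in level. In dyt1 2 alone against wild type 3 alone it was -0.37, a value with no test. Of the remaining lists with at least 3 measured genes, 0 of 3 early anther cell fate genes (median 0.06), 0 of 4 flavonoid genes (-0.62), 0 of 3 gibberellin receptors (-0.18), 0 of 7 maturing pollen genes (-0.05) and 0 of 4 reference genes (0.10) were called; adjusted over the list alone, the flavonoid gene UGT78D1 was higher. In the lists with 1 or 2 measured genes none passed over all probe sets, and adjusted over the list alone AUR2 of the cell cycle (0.61) and the heat shock gene ATHSP22.0 (1.65) were higher and the ovule gene INO (-0.88) was lower.

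In all, 44 of 22746 probe sets were called in dyt1 against wild type, 17 higher and 27 lower (43 with a 2-fold limit), while 3300 had an unadjusted p under 0.05 where chance gives 1137. Each array centred on its median, which shifted the median of all probe sets by -0.11, gave 10 higher and 34 lower. Rises outnumbered falls without dyt1 2 (517 and 185), without wild type 3 and dyt1 2 (2215 and 1505) and within the arrays of low 25S signal (2564 and 1885). They also did with array weights (4750 and 3994) and with a floor at the 20th percentile (54 and 31). The same held among at most 4 calls without wild type 1, dyt1 3 or ams 3, in the test against 1.5-fold and at an adjusted p under 0.01. The count was 3, 6 and 541 without wild type 1, 2 or 3. It was 4, 702 and 1 without dyt1 1, 2 or 3, and 26, 27 and 4 without ams 1, 2 or 3, which enter through the pooled spread. Wild type and dyt1 occur in both library sets, and 274 probe sets were called with the set as a block. Within the 4 arrays of low 25S signal 4449 were called, and 3720 with wild type 3 and dyt1 2 left out. In both settings the spike-ins averaged 3.85 and 3.76 in wild type against 6.67 and 6.99 in dyt1. Genotype cannot be told there from spike-in level. Within the 5 arrays of high 25S signal, or with a block that also separated the spike-in sets, the comparison rests on wild type 3 and dyt1 2 alone. These lone arrays are assumed to vary like the other arrays. Of the 20 genes named for this comparison, AT4G03156 kept its call in all 9 omissions of a single array. None changed sign in any setting, but their dyt1 and wild-type values did not overlap, so leaving out arrays could not turn a sign.

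In the arrays labelled ams, rises outnumbered falls in the planned fit, but not with array weights or without wild type 3, and several genes went from background-like to high levels or back. DELTA-VPE, a vacuolar processing enzyme, rose from 4.56 ± 0.68 in wild type to between 9.72 and 10.3 (log2 change 5.45, SE 0.37, n = 3, adjusted p = 0.000134). AT3G16750, AT2G01090 and AT1G80970 rose by 4.68, 4.38 and 4.29, with adjusted p values of 1.63e-05, 5.43e-06 and 1.75e-05. AT5G38160 (4.26), AT1G06640 (4.06), AT5G45500 (3.95), AT5G56380 (3.93), AT1G09510 (3.63) and the cytochrome P450 CYP71B26 (3.62) also rose. AT1G50290 fell by 4.58 (adjusted p = 0.00164), as did AT2G15220 (-4.28), which a shared probe set represents, AT5G15360 (-4.08), AT4G19240 (-3.79) and AOP3 (-3.70), an oxygenase of glucosinolate synthesis. AT1G58025 (-3.49), AT3G44070 (-3.40), RBOHE (-3.35), AT1G67920 (-3.34) and AT3G24230 (-3.24) also fell, with adjusted p values up to 0.0165. DELTA-VPE, AT3G16750, AT2G01090, AT5G45500, AT1G50290, AT2G15220, AT1G58025 and AT3G24230 had a wild-type or ams mean that cannot be told from background, so the size of their change is not measured beyond the difference of signal.

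The tapetal lists held few called genes in ams. AMS rose and the other 4 tapetum transcription factors did not pass (BHLH091, -1.09, adjusted p = 0.498), and adjusted over the list alone again only AMS rose. Of the 8 genes of tapetal lipid transfer and the pollen coat, 0 passed by either adjustment, with 4 higher and 4 lower: AT5G62080 differed by -4.16 (adjusted p = 0.0945), A9 by -2.74 (adjusted p = 0.305) and ATA27 by 2.30 (adjusted p = 0.301). RBOHE fell while BETA-VPE (1.87, adjusted p = 0.212) and UND (0.10, adjusted p = 0.965) did not pass. UGT78D1, a flavonol rhamnosyltransferase, rose by 0.96 (adjusted p = 0.0179), and the other 3 flavonoid genes did not pass. LHCB4.2, a light-harvesting antenna protein, rose by 1.23 (adjusted p = 0.00908), and LHCB4.1 did not (0.13, adjusted p = 0.727). The 8 meiosis genes had a median of 0.01 with 4 higher and 4 lower, and 0 of them, of 3 early anther cell fate genes (0.12), 3 gibberellin receptors (-0.38), 7 maturing pollen genes (-0.07) and 4 reference genes (-0.03) were called. Adjustment over the list alone called the same genes: AMS, UGT78D1, RBOHE and LHCB4.2. Camera called none of the 9 lists in ams, where the smallest unadjusted p was 0.237, and its sign was opposite to the median for tapetal lipid transfer and the pollen coat (median -0.34), for tapetum transcription factors (median -0.17) and for tapetal cell death (median 0.10).

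The families gave 2 set calls in ams that did not hold with an estimated correlation or by fry. Of 45 glycosyltransferases, UGT88A1 (1.54), UGT71C3 (1.07), UGT71B1 (0.98) and UGT78D1 (0.96) rose, UF3GT (-0.68) fell and 40 did not pass. The set had a median of 0.11 (camera adjusted p = 0.00991, adjusted p = 0.787 with an estimated correlation and 0.183 by fry), which was -0.0018 with each array centred on its median (adjusted p = 0.00813). It was 0.02 without wild type 1 (adjusted p = 0.0303), 0.04 without wild type 2 (adjusted p = 0.0608), 0.31 without wild type 3 (adjusted p = 0.00129) and 0.06 without ams 2 (adjusted p = 0.0188). The median was -0.012 with library set as a block (adjusted p = 0.103) and, as a value with no test, -0.08 against wild type 3 alone. The 69 plastid-encoded genes had a median of -1.06, with 60 lower and 0 called singly (camera adjusted p = 6.51e-05, adjusted p = 0.914 with an estimated correlation and 0.488 by fry). With library set as a block their median was -0.06 (adjusted p = 0.811), and it was -0.41 against wild type 3 alone, given as a value with no test.

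In ams against wild type, 798 probe sets were called, 558 higher and 240 lower (563 with a 2-fold limit), and 4913 had an unadjusted p under 0.05. The division was 708 and 156 with each array centred on the reference genes, which shifted the median of all probe sets by 0.11, and 417 and 332 with each array centred on its median, a shift of -0.11. Falls outnumbered rises without wild type 3 (1866 higher and 2280 lower), without wild type 3 and dyt1 2 (3693 and 4169) and with array weights (3954 and 4962). Once wild type 3 is left out, genotype cannot be told from 25S signal or spike-in level in this comparison. Against wild type 3 alone, assumed to vary like the other arrays, the division was 1454 and 1449 with a block by 25S and spike-in sets and 618 and 583 within the arrays of high 25S signal. All 3 ams arrays had high 25S signal: with library set as a block 843 were called, of which 496 were among the 798, within the 5 arrays of high 25S signal 1201, and with a block that also separated the spike-in sets 2903. The count was 279, 352 and 4146 without wild type 1, 2 or 3, 1624 and 487 without dyt1 2 or 3, 335, 296 and 361 without ams 1, 2 or 3, and 7862 without wild type 3 and dyt1 2. Of the 23 genes named here, 16 kept their call in all 9 omissions of a single array, including DELTA-VPE, AT3G16750, AT2G01090 and AT1G58025. None changed sign in any setting, but their ams and wild-type values did not overlap, so leaving out arrays could not turn a sign.

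Compared directly, dyt1 and ams differed in ATA27, AT1G68875 and AT1G58025, each with 1 mutant at a level that cannot be told from background. ATA27 was at 3.85 ± 0.15 in dyt1 and 10.9 ± 1.60 in ams (log2 difference -7.08, SE 1.19, adjusted p = 0.0151). AT1G68875 (-6.47, adjusted p = 0.00596), AT5G13380 (-5.39), DELTA-VPE (-5.30) and AT1G47980 (-5.05) were also lower in dyt1. AT1G58025 was higher in dyt1 (5.76, adjusted p = 1.12e-05), followed by AOP3 (4.68), AT5G15360 (3.85), AT4G19240 (3.78) and AT2G16960 (3.58). The means of AT5G13380 and DELTA-VPE in dyt1 and of AT2G16960 in ams also cannot be told from background. Their changes are only differences of signal. AT1G58025 rose in dyt1 and fell in ams against wild type, as AT1G42705 did (2.27 and -1.21).

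Among the lists, ATA27 and AT5G52160 (-3.53, adjusted p = 0.0450) of the 8 genes of tapetal lipid transfer and the pollen coat were lower in dyt1 than in ams, and 6 did not pass; adjusted over the list alone, 3 were lower. As a set the list was lower in dyt1 (median -1.86, 7 of 8 lower, camera adjusted p = 0.0137), but not with an estimated correlation (adjusted p = 0.985) or by fry (adjusted p = 0.203). Its shift was -2.52 with library set as a block (adjusted p = 0.00157) and, as a value with no test, -3.69 in dyt1 2 alone against ams, but -1.13 without dyt1 2 (adjusted p = 0.896) and -1.55 without ams 1 (adjusted p = 0.0725). Centred on the reference genes it was -2.04 (adjusted p = 0.168). AMS was lower in dyt1, and the other 4 tapetum transcription factors did not pass. LHCB4.2 was lower in dyt1 (-1.01, adjusted p = 0.0191), and MGH3, a histone of male gametes, was higher (0.93, adjusted p = 0.0391). The mean of MGH3 in ams cannot be told from background, and MGH3 lost its call in 13 of 21 other settings. SHT, which makes spermidine conjugates for the pollen coat, differed by -3.87 (adjusted p = 0.111). SHT, the heat shock gene ATHSP22.0 (2.53, adjusted p = 0.0836) and the reference gene TIP41 (0.60, adjusted p = 0.0635) passed only when adjusted over the list alone. The sugar transporter family was also called by camera (median -0.09, 11 of 17 lower, adjusted p = 0.0301, adjusted p = 0.787 with an estimated correlation and 0.298 by fry), and SAG29 was lower (-2.66, adjusted p = 0.0240). Its shift was -0.55 with library set as a block (adjusted p = 4.65e-06) and, as a value with no test, -0.66 in dyt1 2 alone against ams. It lost the call without dyt1 2 (-0.11, adjusted p = 0.372), ams 1 (-0.14, adjusted p = 0.0747) or both wild type 3 and dyt1 2 (-0.11, adjusted p = 0.355). It also lost it with each array centred on the reference genes (-0.26, adjusted p = 0.115) and with a floor at the 20th percentile (adjusted p = 0.0638). Without dyt1 1, dyt1 3, ams 2 or ams 3 it kept the call at -0.40, -0.41, -0.44 and -0.15. The 69 plastid-encoded genes had a median of 0.98 (camera adjusted p = 6.51e-05, adjusted p = 0.914 with an estimated correlation and 0.488 by fry), 0.53 without dyt1 1 (adjusted p = 0.0901) and 1.58 without dyt1 2 (adjusted p = 9.44e-20). It was 0.14 with library set as a block (adjusted p = 0.654) and, as a value with no test, -0.21 in dyt1 2 alone against ams.

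Between the mutants 1108 probe sets were called, 557 higher and 551 lower in dyt1 (708 with a 2-fold limit), and 5070 had an unadjusted p under 0.05. Centring on the reference genes, which shifted the median of all probe sets by -0.18, gave 272 higher and 790 lower. The division was 130 and 250 without dyt1 1 and 1224 and 906 without dyt1 2, and without dyt1 3 234 of 357 were lower. It was 114 and 240, 139 and 268, and 133 and 294 without ams 1, 2 or 3, 286 and 422 with a 2-fold limit and 297 and 432 with the sample number as a block. The count was 1085 with library set as a block. With dyt1 2 as the lone dyt1 array, assumed to vary like the other arrays, it was 5580 with a block that also separated the spike-in sets and 3487 within the 5 arrays of high 25S signal. It was 2945 without wild type 3, 380, 2130 and 357 without dyt1 1, 2 or 3, 354, 407 and 427 without ams 1, 2 or 3, and 5958 without wild type 3 and dyt1 2. Of the 14 genes named here, 8 kept their call in all 9 omissions of a single array, among them AT1G58025, AOP3, DELTA-VPE and AMS. None changed sign in any setting, but their dyt1 and ams values did not overlap, so leaving out arrays could not turn a sign.

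With all arrays, the number of probe sets called in the same direction in both mutants was set against lists of the same sizes from simulated unchanged groups. It lay within the range that those lists, taken by the smallest p whether called or not, shared. No such range was computed for the alternatives. AT1G69790 fell in dyt1 and in ams (log2 changes -1.97 and -2.13), as did AT3G23880 (-1.95 and -1.79) and AT3G25260 (-3.68 and -2.37). AT1G12600, AT1G28710, AT1G06250, AT1G65560, AT1G07795 and AT5G50030 also fell in both, and AT1G49580 rose in both (1.34 and 0.82). AMS fell in dyt1 and rose in ams. In all, 23 probe sets fell in both mutants and 2 rose in both, where independent lists of the same sizes would share 0.285 and 0.417, and 2 rose in dyt1 and fell in ams and 1 the reverse. In 100 simulations of unchanged groups against the same wild-type arrays, lists of the same sizes, taken by the smallest p, shared 13 to 31 probe sets in the same direction (mean 23.3). The observed number was 25. Counted by calls instead, the simulated groups shared at most 0, so this range describes ranked lists and not calls. Part or all of the excess over independent lists may come from the shared controls. These were not split, since 3 wild-type arrays are too few to give each mutant at least 2 of its own. Across probe sets the log2 changes correlated at 0.347 against a mean of 0.497 in the simulations, and their covariance was 0.103 against 0.0600. The overlap in the same direction was 62 with library set as a block. With wild type 3 and dyt1 2 as lone arrays of their genotypes, it was 1314 with a block that also separated the spike-in sets and 529 within the arrays of high 25S signal. It was 1, 4 and 376 without wild type 1, 2 or 3, 1, 215 and 0 without dyt1 1, 2 or 3, 14, 9 and 1 without ams 1, 2 or 3, and 2135 without wild type 3 and dyt1 2. Shared rises outnumbered shared falls without dyt1 2 (147 and 68) and without wild type 3 and dyt1 2 (1156 and 979). Once wild type 3 is left out, all mutant arrays differ from the wild-type arrays in spike-in level.

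Genes near the mutated loci were counted as a check on DNA carried along with each mutation. Leaving out AMS itself, 0 of 422 genes within 500 genes of the DYT1 locus fell in dyt1, against 14 of 12932 elsewhere (Fisher's exact test, 2-sided, p = 1), and 1 rose, AT4G22390 (1.69, adjusted p = 0.0239). Of 417 genes near AMS, 3 fell in ams, against 141 of 12937 elsewhere (odds ratio 0.658, 95% interval 0.133 to 1.98, exact p = 0.632). AT2G16960 and EXPB1 rose in dyt1 and lie near AMS. Near AMS 2 of 417 genes rose in dyt1, against 8 of 12937 elsewhere (odds ratio 7.79, exact p = 0.0371, adjusted p = 0.445). AT2G16990 (3.16), AT2G16890 (3.39) and AT2G16900 (2.51), also near AMS, rose in ams. These last 3 genes were chosen after their values were seen. None of the 12 tests of this kind passed after adjustment. They count all genes within 500 genes of a locus and leave out AMS, so an effect limited to the closest genes could be missed.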

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

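The tests of arrays standing apart in this part were chosen after the results were seen; the splits of the arrays were planned. The control probe sets, which entered no comparison except in 1 alternative that kept them, differed between groups: the lowest array of the mutant lay above the median wild-type array. The poly-A spike-ins were higher by 2.06 in dyt1 and 1.82 in ams on the log2 scale, and the hybridization spike-ins by 0.0813 and 0.206. In ams the 25S ribosomal RNA probe set was higher by 2.81, and the difference between the 3' and 5' probe sets was larger by 1.00 for actin and 0.207 for GAPDH. These differences did not follow genotype alone: wild type 3 was at 2.81 for actin and 0.791 for GAPDH, against 2.67 to 2.92 and 0.443 to 0.692 in ams, and dyt1 2 was at 2.103 for actin against 1.04 and 1.38 in dyt1 1 and 3, but at 0.290 for GAPDH, below the ams arrays and near wild type 2 (0.252). With 3 arrays per group no test for outlying arrays was made.

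Other splits of the arrays gave a structure that crossed the genotypes. Of the 10 splits of the wild-type and dyt1 arrays into 3 and 3, 2 called at least 44 probe sets: the real one and the split of wild type 1 and 2 with dyt1 2 against the rest, which called 372. That split calls several times the real count and points to a structure of the samples. It equals an exchange of wild type 3 and dyt1 2, and dyt1 2 correlated across probe sets at 0.933 and 0.945 with wild type 1 and 2 against 0.929 and 0.939 with dyt1 1 and 3. Wild type 3 correlated at 0.939 and 0.930 with wild type 1 and 2 against 0.928 and 0.934 with dyt1 1 and 3. The split does not part the arrays by library set. With library set as a block, 274 probe sets were called in dyt1 against wild type, and probe sets that differ between the library sets were not counted. For ams against wild type only 1 split of 10, the real one, called 798, and the highest other called 10; for dyt1 against ams only 1 split, the real one, called 1108, and the highest other called 0. With 10 splits no share under 0.05 can be reached.

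The low count in dyt1 against wild type went with wild type 3 and dyt1 2, each far from its group, and the pair correlated least of all pairs of arrays (0.902). A library effect shared by both arrays is argued against only as the main source of their shifts from the other arrays of their group. These shifts correlated at -0.0528 over all probe sets. A smaller shared part is not excluded, since the plastid-encoded genes were lower in both (-0.94 and -1.73). The 5S ribosomal RNA probe set was also lower, at 6.85 in wild type 3 and 7.42 in dyt1 2. It lay at 8.16 to 10.7 in the other arrays of these genotypes. An exchange of the 2 arrays is argued against for tapetal genes but not excluded. The 100 named genes that fell most in dyt1 1 and 3 against wild type 1 and 2 were taken. Of these, 93 were also lower in dyt1 2 than in wild type 3, which an exchange would turn. Of the 100 that rose most only 18 were higher, which goes with an exchange. In the arrays used to pick both sets, genotype cannot be told from spike-in level. The list of tapetal lipid transfer and the pollen coat was fixed beforehand. It was the only fixed list called between those arrays (-1.88), and it was also lower in dyt1 2 than in wild type 3 (-6.30). AMS also followed the labels, at 3.96 in dyt1 2 and 7.55 in wild type 3, as did ATA27 (3.69 and 11.6), chosen after its values were seen. A candidate explanation for wild type 3 is anthers of another stage within the sampled range: the meiosis list lay at -0.99, with 8 of 8 genes lower, below all 10000 random lists of like level. For dyt1 2 the meiosis list lay at -0.42 (percentile 3.24), which leaves its stage open.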

How the results depend on the processing

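The alternatives by library set, by 25S and spike-in sets and without both wild type 3 and dyt1 2 were chosen after seeing the data, and the cause of a difference was not tested unless named. Against counts of 44, 798 and 1108 for dyt1 against wild type, ams against wild type and dyt1 against ams and 25 for both mutants in the same direction, array weights gave 8744, 8916, 8956 and 3883. Leaving out 1 array gave 1 to 702, 279 to 4146, 354 to 2945 and 0 to 376, and leaving out both wild type 3 and dyt1 2 gave 3720, 7862, 5958 and 2135. Library set as a block gave 274, 843, 1085 and 62, and 25S and spike-in sets as a block 4698, 2903, 5580 and 1314. Within the 5 arrays of high 25S signal the counts were 2544, 1201, 3487 and 529, and within the 4 of low 25S signal 4449 for dyt1 against wild type. Within the low 25S arrays, and without wild type 3 and dyt1 2, wild type and dyt1 cannot be told from their spike-in levels. The sample number as a block gave 54, 545, 729 and 30. Arrays of the same number paired weakly at most. Their deviations from the group means correlated at -0.0120 to 0.237. Among arrays of the other genotypes, 5 of the 9 arrays correlated best with one of their own number. For dyt1 against wild type, quantile normalization gave 29 and a floor at the 20th percentile 85, with 40 in both mutants. The filter on dim probe sets tested 13647 and gave 428 in ams and 675 between the mutants. Fits to only the 2 groups compared gave 8 for dyt1 against wild type and 1979 between the mutants. Stricter calls gave fewer by construction: a 2-fold limit 708 between the mutants, a test against 1.5-fold 3, 168, 183 and 1, and an adjusted p under 0.01 3, 259, 289 and 1. Without genes near the loci 22 were called in dyt1 and 14 in both mutants; 4 of the 44 lay near them. All other counts stayed within 1.5 times.

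AMS kept its direction in all settings, at -3.36 to -2.51 in dyt1, 1.63 to 1.82 in ams and -5.08 to -4.23 between the mutants when 1 array was left out. Its adjusted p over these ranged from 0.00560 to 0.164, 0.00557 to 0.146 and 0.000181 to 0.00317. It also lost its call in dyt1 with only the 2 groups compared (-2.93) and in ams with arrays centred on their medians (1.61). The list of tapetal lipid transfer and the pollen coat ranged from -4.28 to -1.92 in dyt1 against wild type and from -2.50 to -1.13 in dyt1 against ams when 1 array was left out. Its calls were lost with an estimated correlation (-3.54 and -1.86) and without both wild type 3 and dyt1 2 (-1.88 and -1.13), and in dyt1 against ams with reference centring (-2.04). Lists and families gained a call 3 times when 1 array was left out and 7 times in the added settings. In dyt1 against wild type these were the plastid-encoded genes without dyt1 1 (-0.38) and glycosyltransferases within the low 25S arrays and without both wild type 3 and dyt1 2 (0.16 in each), and in dyt1 against ams glycosyltransferases without dyt1 3 (-0.05) or ams 3 (-0.11). The other 5 rest on wild type 3 or dyt1 2 as a lone array. The plastid-encoded genes turned the direction of their set test in dyt1 against wild type without dyt1 2 (0.59, the highest with 1 array left out, against a lowest of -0.38) and without both arrays (0.31), in ams with library set as a block (-0.062), and in dyt1 against ams with that block (0.14), with the 25S and spike-in block (-0.21) and within the high 25S arrays (-0.21). Calls of single named genes were kept 336 times and lost 150 times when 1 array was left out. They were kept 428 and lost 45 times in the other planned settings, and kept 224 and lost 11 times in the added ones. No sign changed, which for omissions of arrays was fixed in advance, since the values of the groups compared did not overlap in these genes. Dim probe sets are limited by their signal over background, and a block for slide or scan date was not run.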

Other observations

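The tests of the ams arrays and of accession in this part were chosen after the results were seen; those of genes lower near the DYT1 and AMS loci were planned. Genes outside the naming rule, chosen after their values were seen, also stood apart in ams. PAP20, a purple acid phosphatase, was at 9.76 in ams against 6.12 in wild type and 6.18 in dyt1, LUL1 at 7.44 against 4.07 and 4.00, and the beta-glucosidase gene BGLU28 at 7.24 against 4.47 and 4.48. The MADS-box gene AGL42 was at 5.36 in ams against 7.95 and 8.26.

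Wild type 3 stood above the other wild-type arrays in single genes chosen after their values were seen, while the 3 tapetal lists with at least 3 measured genes did not lie above the range of random lists. ATA27 was at 11.6 in wild type 3 and 7.16 and 7.13 in wild type 1 and 2, SHT at 10.3 against 5.01 and 5.69, and AT1G68875 at 11.1 against 7.86 and 7.32. The list of tapetal lipid transfer and pollen coat genes lay at 0.36 in wild type 3 (percentile 92.1), and the 5 tapetum transcription factors at -0.90, with 4 lower (percentile 0.93). The flavonoid list lay at 1.03 there, with 2 higher and 2 lower (percentile 98.7). In dyt1 2 the first list lay at -1.67 against dyt1 1 and 3, with 7 of 8 genes lower (percentile 0.02 among 10000 random lists of like level, as for the other percentiles). Random lists hold unrelated genes, so the percentile of a list whose genes vary together may overstate how unusual its shift is.

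In 100 probe sets all 3 ams arrays lay more than 1.5 log2 units beyond all other 6 arrays, 83 above and 17 below. Chance choice of arrays is argued against, since only 1 of the 84 ways to take 3 arrays of 9, the ams arrays themselves, gave as many, and the next highest count, reached by 2 other choices, was 29. DNA linked to the AMS locus is argued against as the whole source, since 2 of the 64 named genes lie within 500 genes of it and 62 outside. For the library set this count cannot decide. Wild type 3 and dyt1 2 share the high 25S signal of ams, so the choice of probe sets leaves out an effect equal in all 5 arrays. The other 9 ways to take 3 of these 5 arrays gave at most 16. Of 204 probe sets in which the ams arrays lay as far beyond the 4 arrays of low 25S signal, wild type 3 and dyt1 2 were both nearer to those 4 in 57.4%, both nearer to ams in 19.6% and divided in 23.0%. Another accession across the genome, with AOP3 at -3.70 among them, or a batch of the ams arrays alone may be a source, and neither can be told apart from loss of AMS because all ams arrays would share it.

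Of genes lower near the mutated loci, the odds ratio was 0 for DYT1 in dyt1 (95% upper bound 9.26) and 0.658 for AMS in ams (upper bound 1.98), so an excess from linked DNA of another accession was not seen but, at these bounds, not excluded.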
